A study of Homo sapiens with 27 samples.

How the data were processed

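The series held 27 libraries of HL-60 cells, each the sole library of its group, and groups were taken from the titles and treatment labels. Files were used for 8 gene tables (3 of input DNA, 1 of total RNA and 4 of nascent RNA) and 13 peak lists (10 of ChIP and 3 of RIP). The 6 libraries with control IgG antibodies, 3 of ChIP and 3 of RIP, were not analysed here. Per the labels' protocols, new RNA was isolated with a click-chemistry capture kit, ChIP used formaldehyde-fixed and sonicated chromatin, and RIP recovered RNA with the same antibodies and with one to Tip60. DRB was given at 100 µM and ActD at 0.8 µM. The length of treatment was not given in the sources used here.

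Per the submitters' processing notes, the genome build was GRCh38 and the tools included FastQC, Trim Galore, cutadapt, STAR 2.5.2b and HOMER. The quantifier and annotation behind the gene tables were not given in the sources used here. Per the file headers, the gene tables hold gene and transcript identifiers, lengths, effective lengths, expected counts, TPM and FPKM. The deposited expected counts were used as the measure of abundance, and the deposited TPM and FPKM values were not used, since they keep no depth. The 3 input tables hold their values packed into 1 field and were separated into the same columns. Expected counts need not be whole, so they were rounded for intervals.

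Per the file headers, the peak lists are output of HOMER's peak finder, with a position, a normalized tag count, a find-peaks score, a tag count of the sample and of a control, a fold over control and a p-value for each peak. In the deposited lists every peak has a fold over control of at least 4 and a p-value of at most 0.0001. The deposited headers do not say which library was the control. In 10 lists the tags of the immunoprecipitation had been scaled down to the size of the control, and in 3 lists (H2A.Z siMyc, H2A.Z siNTC and acH2A.Z siMyc) the control had been scaled to the immunoprecipitation. The authors called peaks per library, so differences in depth and in scaling move the number of peaks called. The deposited tag counts are signal values, which the headers name as normalized without giving the scale. Tags per 10000000, which is HOMER's default, was assumed wherever tag counts or shares of tags are compared between lists. The deposited score and fold were used only to rank or limit peaks within a list.

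Expected counts were converted to CPM over all genes of a table, and the log2 ratio of 2 libraries was taken after adding a pseudocount of 1 CPM. Genes were kept with a mean of at least 1 CPM and a sum of at least 20 counts over the libraries of the comparison, and counted as higher or lower at a log2 ratio of at least 1 in size, that is 2-fold. There were no replicates, so no p-value was computed and a ratio compares libraries, not conditions. Exact 95% binomial intervals of the ratio of counts and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. The floor stood at 0.208 CPM in DMSO, 0.209 in DRB, 0.238 in ActD, 0.119 in untreated nascent RNA and 0.237 in total RNA. A fold against 0 counts was taken against this floor and written as "at least". Genes above 0 numbered 16238, 13116 and 12594 in nascent RNA of DMSO, DRB and ActD, 33685 in untreated nascent RNA and 18192 in total RNA. The most abundant RNA was MT-RNR2 with 23.5%, 35.3% and 47.4% of counts in DMSO, DRB and ActD, and RN7SL1 with 26.7% of untreated nascent and 21.7% of total RNA counts, so CPM values of all other genes depend on these. The scale was therefore also set by centring on the median gene and by rescaling without mitochondrial, ribosomal RNA and RNA polymerase III genes.

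Each of 21 gene lists fixed before the data were examined was described by its median log2 ratio, set as a percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists covered immediate early and labile transcripts, MYC targets, S-phase genes, G2/M genes, replication-dependent histones, promyelocyte granule genes, myeloid transcription factors and receptors, neutrophil and monocyte genes, erythroid, lymphoid, and epithelial and fibroblast markers, ribosomal protein genes, mitochondrially encoded genes, RNA polymerase III transcripts, snoRNA host genes, nuclear long non-coding RNAs, H2A.Z, SRCAP and TIP60 complex genes, p53 targets, apoptosis regulators, NF-kappa-B and inflammatory genes, and housekeeping genes. Where members had 0 counts in a library, the median was also taken with them at their bound. Named genes followed a rule fixed at the same time. It took the 10 highest and 10 lowest genes with at least 100 summed counts, up to 2 highest and 2 lowest members of each list, and 12 fixed genes. For peaks it took the 5 peaks with the highest score per list and the 10 genes with the highest score among those with an end peak in 1 list and none in the other, and for input DNA the 5 highest genes. Not every gene that the rule admits is printed, and a few are not reported here.

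Gene positions came from a RefSeq gene table on GRCh38, which gave coordinates for 39877 of 58233 genes, and 57392 identifiers matched a symbol. Peak comparisons used the 19052 protein-coding genes with coordinates and peaks on chromosomes 1 to 22, X and Y. The planned measure was a peak within 1000 bp of a transcription start. The gene table gave no strand, so a peak within 1000 bp of either gene end was counted. Peaks sharing at least 1 bp were called overlapping, with peaks shifted by 500000 bp as background. Gene overlaps were set against the product of the list sizes divided by the number of genes. For RIP, a peak anywhere in the gene body was counted. Shares have 95% Wilson intervals. Gene length is the RefSeq span, known for 91.2% of the genes tested. Input DNA was expressed per base relative to the median gene and summed over windows of 10 neighbouring genes. Genes that overlap, are read through or have near-identical copies can share reads, and the counting was not stated to use strand.

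Unchanged libraries, DMSO included, were simulated with counting error only, to give the correlation that a shared DMSO library produces through such error, in 20 repeats. The ratio step was tested on simulated data with 200 genes changed 4-fold. The changed genes were drawn only from genes well counted in DMSO, and the simulated spread was counting error alone. The test therefore does not cover lowly counted changed genes or spread beyond counting. For DRB against DMSO, on 12438 genes, 100% of the changed genes were called in each direction, 0 unchanged genes were called and 96% of intervals held the simulated ratio, and for ActD, on 12504 genes, these were 100%, 0 and 96.5%.

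The alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 CPM, centring, rescaling, the higher-scoring part of each peak list, lists limited to the length of the shortest, reciprocal overlap of 50%, ends of 500 or 2500 bp, total RNA or gene length in place of nascent RNA for ranking, and genes of at least 5000 bp for input DNA. A limit to peaks above the highest of the compared lists' lowest tag counts was added after the data were seen, as were RIP shares averaged over deciles of gene length, with at least 20 genes in each, RIP shares set against all genes with no RNA counts, and the RIP share of each list that its genes' lengths would give, from all protein-coding genes in the same of 20 bins of gene length. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.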

Results

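HL-60, an established human promyelocytic leukaemia cell line, was profiled in 27 libraries, with 1 library per group and no replicates. Total RNA and nascent RNA were sequenced from untreated cells, and nascent RNA also from cells given the vehicle DMSO, 100 µM DRB or 0.8 µM actinomycin D (ActD). DRB is a kinase inhibitor that holds back elongation by RNA polymerase II, and ActD is a DNA intercalator that blocks transcription. Chromatin immunoprecipitation (ChIP) of the histone variant H2A.Z and of its acetylated form (acH2A.Z) was available for the same 3 treatments and for cells labelled siMyc or siNTC. RNA immunoprecipitation (RIP) of H2A.Z, acH2A.Z and Tip60, the acetyltransferase encoded by KAT5, was available for untreated cells. The nascent libraries held 14426368 expected counts under DMSO, 14339264 under DRB and 12600067 under ActD. The untreated nascent library held 25167597 and the total RNA library 12679342. The input DNA libraries were shallow, with 455948, 440923 and 469547 expected counts over genes under DMSO, DRB and ActD. Mitochondrial genes took 45.9% of the nascent counts under DMSO, 66.5% under DRB and 56.9% under ActD, against 0.560% in untreated nascent RNA. Ratios below are log2 ratios of counts scaled to a common library total (CPM) with 1 CPM added, and "higher", "lower", "rose" and "fell" are used of differences of at least 2-fold. These ratios, also after centring or rescaling, are relative to the other RNA of the same library. A loss of new RNA common to all genes would not show, and a gene that rose may only have fallen less than others. Intervals in brackets are 95% intervals of the ratio of counts without the added CPM, so they can lie outside it, and they cover counting error only. Tag counts of peaks are as deposited, on the assumption that they are per 10000000 tags.

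The first question was what blocking elongation with DRB did to newly made RNA. On the CPM scale most measured G2/M, early response and inflammatory genes fell in DRB, while most replication-dependent histone genes rose. MYC, a gene for a growth-promoting transcription factor, dropped from 153 to 1.12 CPM, a log2 ratio of -6.19 [-7.91, -6.40]. The mitotic kinase gene AURKA dropped from 198 to 1.26 CPM, with -6.47 [-8.06, -6.64]. HIST2H2BE went the other way, from 408 to 2071 CPM, with 2.34 [2.30, 2.38]. Of 12121 genes, 1103 were higher and 6632 lower, or 3013 and 3204 after centring, and the median gene stood at -1.19. Higher genes made up 14.3% of the called genes on the CPM scale, 48.5% after centring on the median gene and 26.4% after rescaling without mitochondrial, ribosomal RNA and RNA polymerase III genes, so list medians are also given relative to the median gene.

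Of 41 measured G2/M genes, 39 fell in DRB and 0 rose, with a median of -2.61, or -1.43 relative to the median gene, below all 10000 random lists matched on expression. CKS2 stood at -5.65 [-7.13, -5.78], whereas HMGB2 at -0.94 and CENPA at -0.89 stayed within 2-fold. Of 59 S-phase genes 37 fell and 0 rose, with a median of -1.43, at -0.25 relative to the median gene and percentile 0.540 among random lists. After centring 8 were higher and 14 lower, and after rescaling 4 and 21. E2F8 at -4.46 and EXO1 at -4.05 were lowest, and the polymerase genes POLD1 at 0.72 and POLA1 at 0.60 were highest. Among 32 immediate early and labile transcripts 25 fell and 1 rose. Their median was -2.17, or -2.31 with genes at 0 counts set to their bound, at -0.98 relative to the median gene and percentile 0.280. IER2 rose by 2.13 [1.97, 2.58], and ZFP36L1, with 3 counts in DRB, stood at -4.72 [-9.49, -5.65]. All 17 apoptosis regulators fell, with a median of -2.31, or -1.12 relative to the median gene, at percentile 0.970, and DIABLO at -3.13 and CASP8 at -1.26 spanned the range. Of 13 genes of the NF-kappa-B and inflammatory list 11 fell and 0 rose, with a median of -2.64, -3.11 with bounds and -1.45 relative to the median gene, at percentile 0.335. IRF1 stood at -4.09 and NFKB1 at 0.39.

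Of 41 measured replication-dependent histone genes 24 rose and 5 fell in DRB. Their median of 1.17, or 2.35 relative to the median gene and 1.90 rescaled, lay above all 10000 random lists. HIST1H3I stood at 2.14, while HIST1H3J was at least 25.4-fold lower and HIST1H4K at least 23.6-fold lower, and reads may be split between near-identical copies. Mitochondrially encoded genes had a median of 0.72, or 1.90 relative to the median gene, also above all random lists, with 2 of 15 higher, MT-ND3 at 1.95 [1.89, 2.02] and MT-CO1 at 1.24. After centring 15 of them were higher, and after rescaling 13. The 7 measured RNA polymerase III transcripts had a median of 0.60, or 1.78 relative to the median gene, at percentile 99.9, with 2 higher. Ribosomal protein genes had a median of -0.48 at percentile 97.6, with 0 higher and 8 lower of 76, and the sign turned to 0.71 relative to the median gene and 0.27 rescaled. RPS26 at -2.93 and RPS16 at -2.72 were their lowest members. Of 43 MYC target genes 21 fell and 1 rose, with a median of -0.93 at percentile 40.8 that turned to 0.25 relative to the median gene. TERT, the telomerase reverse transcriptase gene, rose by 1.44 [1.23, 1.98] and POLR1B stood at -4.25.

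Lineage genes were mixed in DRB. Of 17 myeloid transcription factors and receptors 14 fell and 0 rose, with a median of -1.73, or -0.54 relative to the median gene, at percentile 4.02, led by GATA2 at -4.37 [-5.71, -4.44] and CEBPA at -3.75 [-4.69, -3.71]. The 16 promyelocyte granule genes had a median of -0.78 at percentile 65.8, which turned to 0.41 relative to the median gene, with LYZ at -2.07, IGFBP2 at 1.48 and MPO, myeloperoxidase, at -0.53, which turned to 0.65. Of 9 neutrophil and monocyte genes 7 fell and 1 rose, with a median of -2.02, or -0.83 relative to the median gene, at percentile 24.6. FCGR2A was at least 33.1-fold lower and CXCR2 stood at 1.04. The 5 measured lymphoid markers had a median of -1.47, or -0.29 relative to the median gene, at percentile 48.2, with NKG7 at least 19.2-fold lower. Of the erythroid markers 1 of 19 was measured, and of the epithelial and fibroblast markers 0 of 18.

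Of 27 genes of the H2A.Z, SRCAP and TIP60 complexes 15 fell and 0 rose in DRB, with a median of -1.46 at percentile 7.38, or -0.27 relative to the median gene. KAT5 stood at -3.82 [-6.69, -4.30], and the H2A.Z genes H2AFV at -2.08 and H2AFZ at -0.65, which turned to 0.54 relative to the median gene and 0.09 rescaled. Of 19 snoRNA host genes 15 were lower and 0 higher on the CPM scale, with a median of -1.24 at percentile 27.3, but relative to the median gene the median was -0.05, with 3 higher and 7 lower. Nuclear long non-coding RNAs had a median of -1.07 at percentile 47.4, or -1.21 with bounds, which turned to 0.11 relative to the median gene, with NEAT1 at 1.01 [0.96, 1.08], PVT1 at -0.94, which turned to 0.24, and MALAT1 at 0.03. Of 15 p53 target genes 9 fell and 0 rose, with a median of -1.62, or -0.43 relative to the median gene, at percentile 28.1, AEN at -3.49 and CCNG1 at -3.11. Housekeeping genes had a median of -0.83 at percentile 29.6, which turned to 0.35 relative to the median gene, with ACTB at -1.46 and GAPDH at -0.81, which turned to 0.38. Outside the lists, KIF20A at -5.95, DPF2 at -5.91, KNSTRN at -5.66, TRIB1 at -5.63, SQLE at -5.63 and SRSF2 at -5.62 were among the lowest. GHSR at 6.05 [6.60, 8.97], OSBPL10 at 4.79 and KLHL29, with 2 counts in DMSO, at 4.87 [6.01, 10.92] were among the highest.

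**Figure D1:**
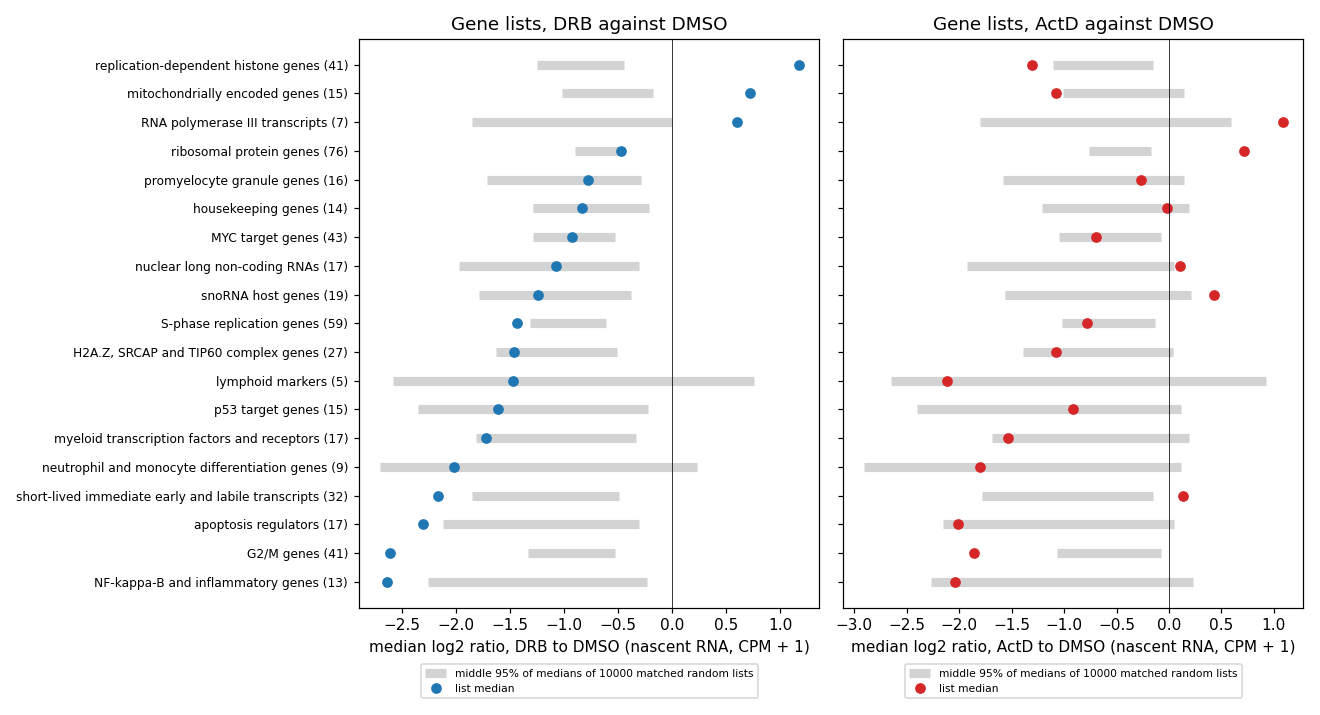
Median log2 ratio to DMSO of nascent RNA for each gene list with measured members in brackets, under DRB on the left and ActD on the right, with grey bars for the middle 95% of medians of 10000 random lists matched on expression. Histone genes stand at 1.17 in DRB and -1.30 in ActD and keep those signs under both other scalings, whereas ribosomal protein genes at -0.48 in DRB turn positive under both.

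ActD was compared with DMSO in the same way. Ribosomal protein genes and snoRNA host genes had list medians above 0 and above nearly all random lists, and the G2/M median lay below all of them. Those random lists were matched on expression and not on gene length. RPL36 rose from 36.5 to 310 CPM, with 3.05 [2.95, 3.22], and the early response genes FOSB at 4.32 [4.30, 5.31] and SGK1 at 4.01 [4.02, 5.15] rose further. MYC stood at 34.8 CPM against 153, with -2.10 [-2.29, -1.99]. Of 12121 genes 1867 were higher and 6077 lower, or 3652 and 3827 after centring, with a median of -1.01. Higher genes made up 23.5% of the called genes, 48.8% after centring and 28.6% after rescaling.

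Of 76 ribosomal protein genes 19 rose and 1 fell in ActD, with a median of 0.71, or 1.72 relative to the median gene, above all random lists. RPL10 stood at 2.03 and RPS16 at -1.72. Of 19 snoRNA host genes 7 rose and 3 fell, with a median of 0.43, or 1.44 relative to the median gene, at percentile 99.3, SNHG8 at 3.86 and SNHG17 at -3.60. The RNA polymerase III transcripts had a median of 1.08, or 2.09 relative to the median gene, at percentile 99.6, with 4 higher and 2 lower, and RN7SK stood at 1.51. Immediate early transcripts divided, with 13 higher and 14 lower of 32 and a median of 0.14 at percentile 99.7, or 1.15 relative to the median gene. ZFP36L2 stood at -3.82 and NFKBIA, with 2 counts, at -3.78 [-9.61, -4.69]. Nuclear long non-coding RNAs had a median of 0.10, or 1.11 relative to the median gene, at percentile 97.8, with HOTAIR at least 24.4-fold higher, CRNDE at 2.51, NEAT1 at 1.29, MIR17HG at least 25.3-fold lower and PVT1, with 1 count, at -3.49 [-12.44, -4.63]. MALAT1 stood at -0.52, which turned to 0.48 relative to the median gene.

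Of 41 G2/M genes 31 fell and 1 rose in ActD, with a median of -1.86, or -0.85 relative to the median gene, below all random lists. AURKA stood at -5.03, CCNB2 at -4.70 and CDCA3 at 1.72. Of 41 histone genes 22 fell and 3 rose, with a median of -1.30, or -0.30 relative to the median gene, at percentile 0.350. After centring 11 were higher and 13 lower. HIST1H2AB stood at -4.16 [-4.66, -4.03] and HIST1H2BE at 2.93. Mitochondrially encoded genes had a median of -1.08, or -0.07 relative to the median gene, at percentile 1.1, with 8 of 15 lower and 1 higher, MT-CYB at -2.12 and the ribosomal MT-RNR2 at 1.01. Of 17 apoptosis regulators 13 fell and 2 rose, with a median of -2.02, or -1.01 relative to the median gene, at percentile 4.97 and within the middle 95% of random lists. PMAIP1, a pro-apoptotic BCL2 family gene, stood at 3.39 [3.28, 3.62]. Of 13 inflammatory genes 10 fell and 2 rose, with a median of -2.04, -2.07 with bounds and -1.03 relative to the median gene, at percentile 7.24 and also within that range, with NFKB2 at 2.81 and NFKB1, with 2 counts, at -4.60 [-10.47, -5.55]. Of 59 S-phase genes 27 fell and 3 rose, with a median of -0.78 at percentile 19.7 that turned to 0.23 relative to the median gene, DTL at -3.87 and CDT1 at 1.89. Of 43 MYC target genes 18 fell and 1 rose, with a median of -0.70 at percentile 32.9 that turned to 0.31, PES1 at -3.64 [-3.97, -3.51] and TERT at 2.39 [2.24, 2.95].

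Of 17 myeloid transcription factors and receptors 13 fell and 1 rose in ActD, with a median of -1.54, or -0.53 relative to the median gene, at percentile 4.97. GATA2 stood at -5.04, CEBPA at -4.77 and CEBPB at 1.79. Granule genes had a median of -0.27 at percentile 83.7, which turned to 0.74 relative to the median gene and 0.13 rescaled, with CFD at 1.96 and MPO at -0.08, which turned to 0.92 and 0.31. The 9 neutrophil and monocyte genes had a median of -1.81 with 7 lower, and the 5 lymphoid markers -2.12 with 4 lower. Relative to the median gene these were -0.80 and -1.11, at percentiles 45.1 and 28.2. The H2A.Z, SRCAP and TIP60 genes had a median of -1.08, or -0.07 relative to the median gene, at percentile 12.3, with 14 of 27 lower and 0 higher. KAT5, with 2 counts, stood at -4.18 [-10.03, -5.11], VPS72 at -3.99, H2AFV at 0.90 and H2AFZ at 0.26. The p53 target genes had a median of -0.92 at percentile 62.2, which turned to 0.09 relative to the median gene, with BTG2 at 3.81 and TIGAR at least 23.3-fold lower. Housekeeping genes had a median of -0.02 at percentile 92.1, which turned to 0.99 relative to the median gene and 0.37 rescaled, with POLR2A at -1.74, GAPDH at 0.40 and ACTB at -0.72, which turned to 0.29 relative to the median gene. METTL13 was at least 207-fold lower, and SQLE at -5.80, SCAF8 at -5.62 and WDR26 at -5.60 followed. NEURL2, with 2 counts in DMSO, stood at 6.37 [7.54, 12.44]. RPL17-C18orf32 at least 758-fold higher and C7orf55-LUC7L2 at least 299-fold lower are read-through genes that share exons with their neighbours, so their values are uncertain.

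Set directly against DRB, ActD held more early response and ribosomal protein RNA and less histone and mitochondrial RNA. JUN stood at 6.32 [6.30, 7.20], PPP1R15A at 5.74, NFKB2 at 5.92 and MYC at 4.08 [4.25, 5.78], and HIST1H2AB at -6.02 [-6.52, -5.90]. Immediate early transcripts had a median of 2.55, or 2.67 with bounds, with 20 of 32 higher and 2 lower, and ribosomal protein genes 1.16, with 46 of 76 higher and 1 lower, both above all random lists. Histone genes had a median of -2.36, with 27 of 41 lower and 4 higher, and mitochondrially encoded genes -1.80, with 13 of 15 lower and 0 higher, both below all random lists. Of 19 snoRNA host genes 15 were higher and 1 lower, with a median of 1.94. G2/M genes had a median of 0.78 at percentile 95.3, with CKS2 at 5.08 and BUB1 at -2.72. CDT1 at 5.41 and SRSF2 at 6.57 were higher, and SNORD3A, with under 1 count in ActD, at -6.37 [-15.39, -7.60], RUSC1 at -6.16 and INO80 at -3.43 lower. Over all genes 3993 were higher and 3261 lower, with a median of 0.10.

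Across genes, the ratios of DRB and ActD to DMSO had a Pearson r of 0.278 and a Spearman rho of 0.290, with a covariance of 0.857. Simulated unchanged libraries, with 1 simulated DMSO library shared by both ratios, gave a mean r of 0.480 and a covariance of 0.0114. Only counting error was simulated, so a shared library with spread beyond counting could give a larger covariance. In both treatments 4004 genes were lower, against 3325 for independent lists, and 186 were higher, against 170. A further 309 were higher in DRB and lower in ActD, and 744 the reverse. Part of the excess may come from the shared DMSO library, which could not be divided, and genes are not independent replicates.

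Nascent and total RNA of untreated cells were compared to see which RNAs differed in share. With 1 library each, of 25167597 and 12679342 counts, an effect of the capture of new RNA cannot be told apart from other differences in preparation. RNA polymerase III transcripts had the highest median of the lists in nascent relative to total RNA. Among the highest single genes were RNU5B-1 at 5.99 [5.95, 7.02], SNORD104 at 4.81 and SNORA31 at 4.09. TERC, the telomerase RNA, at -3.39 [-3.95, -3.37] and NICN1 at -3.71 were low, and SCARNA4 was at least 136-fold lower. Of 13988 genes 1329 were higher and 2484 lower, with a median of -0.34. Higher genes made up 34.9% of the called genes, 56.4% after centring and 56.6% after rescaling. The median of the RNA polymerase III transcripts was 1.29 at percentile 99.99, with 6 of 11 higher and 1 lower, RNU6ATAC at 3.69 and RNY3, with 2.5 counts in total RNA, at 2.10 [2.82, 7.78]. Inflammatory genes had a median of -0.82 at percentile 1.73, or -0.47 relative to the median gene, with 4 of 12 lower and 0 higher, and PTGS2 stood at -1.56.

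The other lists lay within 2-fold between nascent and total RNA. Ribosomal protein genes at -0.17, MYC target genes at -0.10, G2/M genes at -0.13, S-phase genes at -0.18, granule genes at -0.09, snoRNA host genes at -0.16 and mitochondrially encoded genes at -0.19 all turned positive relative to the median gene and rescaled. So did nuclear long non-coding RNAs at -0.24, the H2A.Z, SRCAP and TIP60 genes at -0.23, p53 targets at -0.32 and housekeeping genes at -0.22. Histone genes at -0.31 turned to 0.03 when centred, with HIST1H4J at 2.86 and HIST1H3J at 2.46. Immediate early transcripts at -0.50, myeloid factors at -0.41, neutrophil and monocyte genes at -0.59, lymphoid markers at -0.75 and apoptosis regulators at -0.39 stayed negative. KLF2 at -1.78, KLF4 at -1.57, FAS at -1.93, MDM2 at -1.26 and EXO1 at -1.32 were lower, and FOS at 1.16, NME1 at 1.33, CCNB2 at 1.09 and GINS2 at 1.02 higher. MYC held 178 CPM in nascent and 227 CPM in total RNA, a ratio of -0.34.

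Gene length separated the inhibitors. The shortest decile of genes, with a median length of 2152 bp, stood at -0.73 in DRB and -0.11 in ActD. The fourth decile, at 17058 bp, stood at -1.72 and -1.03, and the longest, at 219313 bp, at -0.24 and -1.27. In DRB 25.4% of the longest genes were lower, against 56.6% in ActD. Spearman's rho with length was 0.153 in DRB and -0.164 in ActD across 11059 genes. The random lists above were not matched on length, so part of the list percentiles may follow from it. Histone genes had a median length of 487 bp and ribosomal protein genes of 5013 bp.

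**Figure D2:**
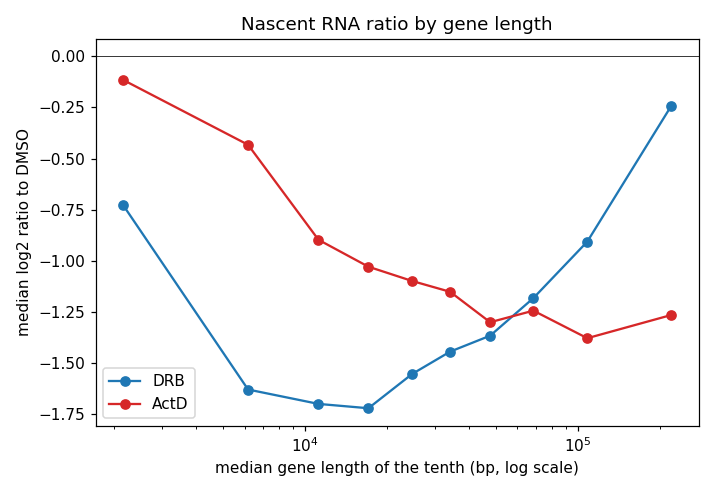
Median log2 ratio to DMSO of nascent RNA in each decile of genes by length, against the decile's median length in bp on a log axis, for DRB in blue and ActD in red. DRB medians run from -0.73 in the shortest genes through -1.72 to -0.24 in the longest, and ActD medians from -0.11 to -1.27, and deciles above the all-gene medians of -1.19 and -1.01 turn positive when centred.

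H2A.Z ChIP was compared between DMSO, DRB and ActD. Ribosomal protein genes had an H2A.Z peak within 1000 bp of a gene end more often than other genes, at 48 of 76 in DMSO, 42 in DRB and 28 in ActD, against 6.16%, 12.4% and 6.17% of all 19052 protein-coding genes. In DRB more histone genes had one, 21 of 51 against 5 in DMSO and 17 in ActD, and more S-phase genes, 20 of 59 against 7 and 5. MYC had no H2A.Z end peak in DMSO or ActD, and one in DRB at chromosome 8, positions 127734620 to 127735644 (GRCh38), with 104 normalized tags. In ActD 1 H2A.Z peak lay in the body of MYC away from its ends, and the siNTC control had an end peak of 1620 tags. A missing call in a list need not mean that H2A.Z was absent. The lists held 1271 peaks in DMSO, 4191 in DRB and 17888 in ActD. Of these 73.4% [70.9, 75.7], 47.3% [45.8, 48.9] and 5.94% [5.60, 6.30] lay at a gene end, as Wilson intervals.

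On the scale assumed for tag counts, H2A.Z peaks held only 0.417%, 0.926% and 1.33% of tags in DMSO, DRB and ActD. The acH2A.Z peaks held 65.4%, 53.7% and 53.2%. The control to whose size the tags were scaled was smallest in DMSO and largest in ActD. Genes with a peak in 1 H2A.Z list and none in another are therefore differences between calls, and an effect of treatment on them was not tested. Genes with an H2A.Z end peak numbered 1174 in DMSO, 2358 in DRB and 1175 in ActD. DMSO and DRB shared 672 of them, against 145 for independent lists, and DMSO and ActD shared 277, against 72.4. RPL15, AURKA, BRIX1, RPS3 and NDUFB5 had a peak in DMSO and none in DRB, and ZNF207, ARNT, NDC80, METTL4 and SNAPIN the reverse. GABPB2, MLLT11, E2F3, RPL32 and GOLPH3 had one in DMSO and none in ActD, and NUP188, PPP2CA, MRPL35 and RICTOR the reverse. TARS2, ARID2 and SRSF3 had one in DRB and none in ActD, and NSRP1, ZMAT2, DDX39B and RPL38 the reverse. Of the other lists in DMSO, DRB and ActD, MYC targets had 11, 15 and 6 of 43, H2A.Z and TIP60 complex genes 4, 11 and 1 of 27, G2/M genes 6, 9 and 4 of 41, and myeloid factors 1, 7 and 5 of 25. The peaks with the highest authors' score lay at GABPB2, RPL15 and E2F3 in DMSO, at RBM8A, RPRD2 and PCBP2 in DRB, and at NR3C1, RBM8A and NSRP1 in ActD. Peaks in ActD were dense on chromosome 18, at 18.6 times the median chromosome, and on chromosomes 5 and 13, at 8.08 and 6.66 times. On chromosome 18 the H2A.Z density was also 6.59 in siNTC and 4.21 in siMyc, but 1.13 in DMSO and 1.99 in DRB. Input DNA in ActD stood at 2.05 times on chromosome 18, 1.18 on 5 and 1.29 on 13. Whether the dense calls follow the input was not tested. The lists of DMSO, DRB and ActD reached down to 17.1, 11.2 and 4.42 tags, on the assumption that the deposited counts are per 10000000 tags. With lists limited to the length of the shortest, 763 genes had an end peak in DRB and 321 in ActD, both below DMSO. With peaks under the highest of these tag counts left out, 1318 genes had an end peak in DRB and 88 in ActD, against 1174 in DMSO. The shared share of DMSO peaks was 51.0% with DRB and 17.6% with ActD, against 1.27% and 2.54% after shifting peaks by 500000 bp. It was 27.3% and 9.35% with lists of equal length, 32.4% and 9.83% with reciprocal overlap of 50%, and 3.88% with ActD at the common lowest tag count.

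acH2A.Z lists were longer. Nearly all G2/M genes had an acH2A.Z end peak, 41 of 41 in DMSO, 40 in DRB and 38 in ActD, as did the H2A.Z and TIP60 complex genes with 27, 26 and 25 of 27, the ribosomal protein genes with 75, 74 and 74 of 76 and the S-phase genes with 57, 57 and 54 of 59. Neutrophil and monocyte genes had 5, 12 and 9 of 31, granule genes 8, 14 and 11 of 20, and myeloid factors 14, 19 and 15 of 25. Among markers of other cell types, erythroid markers had 3, 4 and 2 of 19, lymphoid markers 6, 9 and 6 of 20, and epithelial and fibroblast markers 2, 3 and 2 of 18. Over all genes 9838 had one in DMSO, 11132 in DRB and 9453 in ActD. With lists of equal length DRB had 7206 and ActD 6622, both below DMSO, and with the common lowest tag count they had 10945 and 8601. With the higher-scoring part of each list, which leaves the lists unequal in length, DRB had 6511 and ActD 6280 against 5132 in DMSO. DMSO and DRB shared 9690 genes, against 5748 for independent lists, and DMSO and ActD 8794, against 4881.

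At MYC the acH2A.Z end peak with the highest score held 710 tags in DMSO (chromosome 8, 127733615 to 127738439), 1581 in DRB (127733385 to 127739287) and 590 in ActD (127734046 to 127737674). These sums are over regions called separately, of different widths, so they do not show a change at 1 site. H2AFZ, H2AFV, MALAT1, NEAT1, KAT5 and GAPDH had an end peak in all 3 treatments. MPO and ACTB had one in DMSO and none in DRB or ActD, and ELANE had none in any list. NAXD, KDM3B, AGER and TRAF7 had a peak in DMSO and none in DRB, and TRANK1, MACC1, ACER1 and LAG3 the reverse. MTA1, CYC1, PKD1 and MBD3 had one in DMSO and none in ActD, and RARA, the retinoic acid receptor gene (chromosome 17, 40309180 to 40357643), GHR and TBL1XR1 the reverse. Among the highest scores were those at REV1, TTLL12 and SEC22B in DMSO, GOLGA8A, TTLL12 and DISC1 in DRB, and REV1, ZNF217 and TTLL12 in ActD. There were 17007, 29432 and 31240 peaks covering 35.0, 50.0 and 49.4 Mb. They held 65.4%, 53.7% and 53.2% of tags with means of 384, 182 and 170 tags per peak, on the same assumption. DRB peaks overlapped 95.1% of DMSO peaks and ActD peaks 85.2%, against 6.16% and 5.36% after shifting, and with the higher-scoring part of each list the shares were 53.8% and 55.2%.

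Peaks were also compared between the libraries labelled siMyc and siNTC, with siNTC taken as the control. The level of MYC RNA in these cells was not analysed here, so the labels could not be checked. MYC targets had an acH2A.Z end peak at 26 of 43 genes in siMyc and 41 in siNTC. Immediate early genes had 15 and 34 of 40, ribosomal protein genes 49 and 70 of 76, G2/M genes 24 and 37 of 41, S-phase genes 31 and 53 of 59 and H2A.Z and TIP60 complex genes 16 and 26 of 27, whereas granule genes had 6 and 6 of 20. At MYC the acH2A.Z peak held 1518 tags in siMyc (127734580 to 127736325) and 3449 in siNTC (127734724 to 127736515), and the H2A.Z peak 952 (127734661 to 127736056) and 1620 (127734721 to 127736316). H2A.Z end peaks went the other way in number, with 19 and 8 of 76 ribosomal protein genes, 12 and 8 of 59 S-phase genes and 11 and 9 of 43 MYC targets.

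Over all genes, acH2A.Z end peaks numbered 5656 in siMyc and 10450 in siNTC, a ratio of 0.541, with 5458 shared against 3102 for independent lists. H2A.Z end peaks numbered 2734 and 1677, a ratio of 1.63, with 1026 shared against 241. CHD7, a chromatin remodeller gene (chromosome 8, 60678740 to 60868028), TERT (chromosome 5, 1253167 to 1295068), TFDP1 and YAF2 had acH2A.Z in siNTC and none in siMyc, and MRPS10, LAT2 and GMNN the reverse. For H2A.Z, EP300, FYN, PLCG1 and MAP3K5 had a peak in siNTC only of the pair, and PIM3, MAPK12, TCFL5 and GNB1 in siMyc only. Among the highest H2A.Z scores were those at PLEKHO1, ANKS6 and NEDD4L in siMyc and MAP3K5, PLEKHO1 and CABLES1 in siNTC, and among the acH2A.Z scores those at JAK1 and GLTSCR1L in siMyc and CHD7, POLR3C and LRRC37A3 in siNTC. The acH2A.Z peaks held 3.55% of tags in siMyc over 12.6 Mb with a mean of 24.5 tags, and 39.9% in siNTC over 24.2 Mb with a mean of 230. The H2A.Z peaks held 2.69% over 6.77 Mb and 2.11% over 4.04 Mb, with means of 24.0 and 30.4. These shares and tag counts rest on the assumption of counts per 10000000 tags, and the control was scaled differently for acH2A.Z siMyc and siNTC. Of siNTC peaks, 48.4% of acH2A.Z and 21.7% of H2A.Z overlapped a siMyc peak, against 1.82% and 0.894% after shifting, and with reciprocal overlap of 50% the acH2A.Z share was 23.2%.

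The marks were then compared with each other in control cells. On the scale assumed for tag counts, H2A.Z peaks held 0.417% of tags in DMSO and acH2A.Z peaks 65.4%. In siNTC these shares were 2.11% and 39.9%. Since acH2A.Z is a form of H2A.Z, a gene with an acH2A.Z peak alone need not lack H2A.Z. The numbers of genes therefore do not show how common each mark is. In DMSO all 1174 genes with an H2A.Z end peak also had acH2A.Z, against 606 for independent lists. With lists of equal length, however, 880 genes had acH2A.Z against 1174 with H2A.Z. TTLL12, SEC22B, UBTF, a gene for an RNA polymerase I factor, and NMD3 had some of the highest acH2A.Z scores among genes without an H2A.Z end peak. In siNTC 1627 of 1677 genes had both, against 920, and TRAF3IP1, FAM222A, PGBD5 and IRF2BP2 were among the 50 with H2A.Z alone. Of H2A.Z peaks, 89.5% in DMSO and 31.2% in siNTC overlapped an acH2A.Z peak, against 2.22% and 1.22% after shifting. With lists of equal length these shares were 7.92% and 15.1%, with reciprocal overlap of 50% 0.951% and 6.99%, and with the higher-scoring part of each list 43.7% in DMSO.

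End peaks were set against nascent RNA in DMSO. In the most highly expressed decile of genes 94.0% had an acH2A.Z end peak in DMSO, 94.8% in DRB and 91.9% in ActD, and in the lowest decile 8.81%, 16.6% and 10.6%. The siNTC library gave 92.2% and 12.5%, and siMyc 56.7% and 5.30%. H2A.Z end peaks were found at lower shares, with 22.6% in DMSO, 33.4% in DRB and 14.6% in ActD in the highest decile and 0.262%, 1.31% and 2.83% in the lowest. In siNTC and siMyc the highest decile had 15.6% and 24.7% and the lowest 2.05% and 3.20%, and the eighth decile had 16.4% and 26.0%, so the shares did not peak in the highest. With the higher-scoring part of the list, 47.1% of the highest decile had acH2A.Z in DMSO. The first 4 deciles had a median of 0 CPM, so the order among them is arbitrary.

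**Figure D3:**
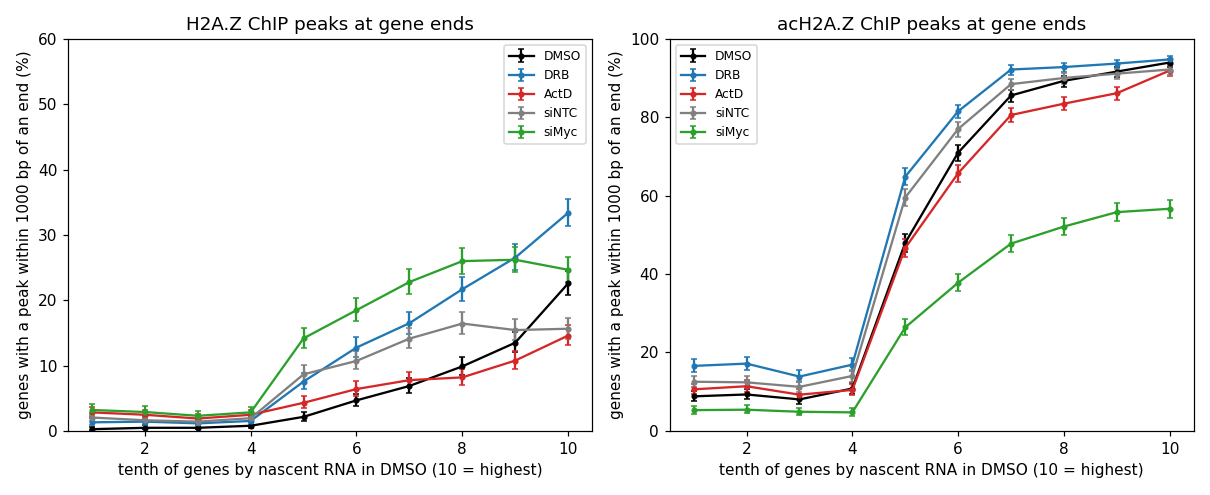
Percent of protein-coding genes with an H2A.Z (left) or acH2A.Z (right) peak within 1000 bp of a gene end, by decile of nascent RNA in DMSO, for each treatment, with 95% Wilson intervals of counting error. acH2A.Z shares in the highest decile run from 56.7% in siMyc to 94.8% in DRB, and the first 4 deciles have a median of 0 CPM and an arbitrary order.

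Genes that kept an acH2A.Z end peak in DRB had a median nascent ratio of -1.33 over 8350 genes, below all 10000 matched random lists. The 111 that lost it stood at -1.40 and percentile 23.3, the 635 that gained it at -0.81 and the 944 with none at -0.72, the last 2 groups above all random lists. In ActD the 7717 genes that kept it stood at -1.09 and percentile 0.0600, the 744 that lost it at -1.04 and percentile 99.3, and the 284 that gained it at -1.47 and percentile 52.4. The 1295 genes with none in DMSO or ActD stood at -1.04, above all random lists. Random lists were matched on mean expression over DMSO, DRB and ActD, and end peaks in DMSO go with expression in DMSO. Part of these percentiles may therefore follow from the matching. With the higher-scoring part of each list, the difference of lost less kept genes turned to 0.017 in DRB and -0.17 in ActD. For H2A.Z in DRB, genes that kept, lost or gained an end peak stood at -1.43, -1.34 and -1.31, and in ActD at -0.79, -1.0 and -1.15. All of these genes had medians of -1.26 in DRB and -1.09 in ActD. Differences from these do not change with centring, but can change with rescaling, because 1 CPM is added before the log.

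RIP asked which RNAs were recovered with H2A.Z, acH2A.Z and Tip60. The small nuclear RNA RN7SK, which has many near-identical copies, had a peak with H2A.Z of 2413 tags (chromosome 6, 52995526 to 52996151), and MALAT1 had one of 425 tags. PVT1, the long non-coding neighbour of MYC, held 24, 26 and 41 peaks in its body with H2A.Z, acH2A.Z and Tip60, and MYC 1, 2 and 3. The counts of these 2 genes were not set against gene length or input DNA, so they do not show enrichment. S-phase genes, with a median length of 33624 bp, held a body peak at 51, 50 and 52 of 59 genes, where genes of the same length would give 39.6, 50.0 and 51.5. Histone genes, with a median of 487 bp, held one at 10, 3 and 4 of 51, where length would give 4.02, 10.9 and 9.11, and ribosomal protein genes, with 5013 bp, at 32, 15 and 28 of 76, or 42.1%, 19.7% and 36.8%, where it would give 21%, 46.0% and 44.5%. Over all genes the shares were 59.5%, 76.3% and 77.3%. Lymphoid markers held one at 11, 18 and 17 of 20, epithelial and fibroblast markers at 6, 12 and 11 of 18 and erythroid markers at 2, 8 and 7 of 19, and of these lists 5, 0 and 1 genes reached 1 CPM in total RNA.

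The highest H2A.Z RIP scores lay at LYPD8, RN7SK, LINGO1, IGF2R and SNORD3A. For acH2A.Z they included ZNF407, an intergenic region of chromosome 10 (130207283 to 130208158) and NCF4 (chromosome 22, 36872243 to 36873645). For Tip60 they included an intergenic region of chromosome 4 (555131 to 556010) and MAEA (chromosome 4, 1323878 to 1326291). The lists held 99234, 264469 and 249628 peaks over 58.9, 193 and 184 Mb, with 3.08%, 3.87% and 3.60% at a gene end. Of H2A.Z RIP peaks 13% overlapped an acH2A.Z RIP peak, against 15.1% after shifting, and 21.3% a Tip60 peak, against 14.6%. Of acH2A.Z peaks 31.2% overlapped a Tip60 peak, against 16.2%. With lists of equal length these shares were 4.29%, 9.51% and 18.9%. All 3 body lists shared 9761 genes, against 6685 for independent lists, and 2372 genes were in none.

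RIP recovery was set against untreated nascent RNA. Body peaks of H2A.Z were found in 31.0% of genes in the lowest decile and 84.0% in the highest. For Tip60 these shares were 53.9% and 85.4%. For acH2A.Z they were 59.5% and 74.6%, with 85.8% in the fourth decile. Gene length differed between these deciles, with medians of 9463 bp in the lowest, 34967 bp in the fourth and 35553 bp in the highest, and in both the lowest and the highest the longest genes held a body peak more often than the shortest. As a mean over deciles of gene length, the shares in the lowest and the highest decile of expression were 48.9% and 78.4% for H2A.Z and 70.2% and 77.9% for Tip60, and for acH2A.Z the direction turned, with 74.7% and 66.6%. From the seventh decile of gene length upward the acH2A.Z direction did not turn, with 93.6% and 100% in the longest decile. Genes with a RIP peak carried acH2A.Z at their ends in DMSO more often than genes without, by 16.5 percentage points for H2A.Z RIP (58.3% against 41.8%), 3.22 for acH2A.Z RIP (52.4% against 49.2%) and 16.2 for Tip60 RIP (55.3% against 39.1%). Within deciles of nascent RNA the mean differences were -2.10, -3.84 and -1.96 points, so the difference did not hold at matched expression. Within deciles of gene length, in contrast, the mean difference stood at 19.1 points for H2A.Z RIP and 16.2 for Tip60 RIP, and at -3.14 for acH2A.Z RIP. For H2A.Z end peaks the mean differences within deciles of nascent RNA were -0.452, -2.60 and -2.20 points.

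**Figure D4:**
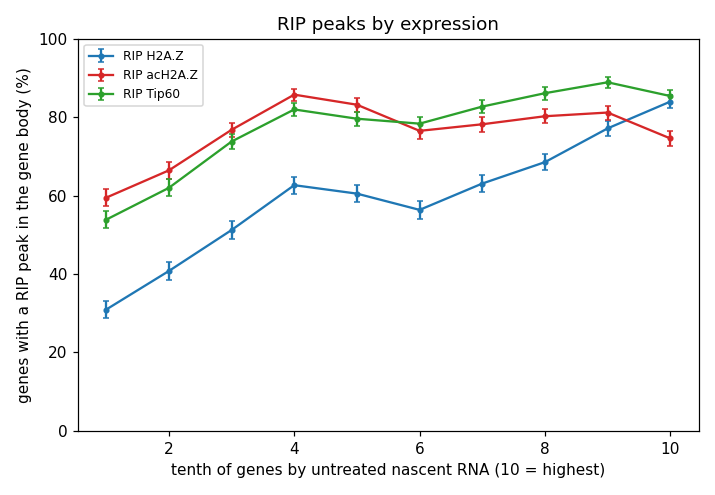
Percent of protein-coding genes with a RIP peak in the gene body, by decile of untreated nascent RNA, for H2A.Z, acH2A.Z and Tip60, with 95% Wilson intervals of counting error. H2A.Z runs from 31.0% to 84.0% and Tip60 from 53.9% to 85.4%, while acH2A.Z runs from 59.5% through 85.8% in the fourth decile to 74.6%, a direction that turns in the mean over deciles of gene length.

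Input DNA, the background of the ChIP libraries, was uneven along the genome. MYC held 8.37, 9.36 and 8.71 times the median gene's input per base in DMSO, DRB and ActD, from 100, 109 and 111 counts. The highest genes were PDE4DIP at 24.7, 29.5 and 22.7, DNM1 at 12.1, 13.3 and 31.1, CBWD5 at 15.2, 15.4 and 10.2, SCAF11 at 12.7, 11.5 and 11.5 and POLR2J3 at 10.7, 11.9 and 11.7, of which CBWD5 and POLR2J3 have near-identical copies. Of 1893 windows of 10 neighbouring genes, 8 were at least 3 times the median in all 3 libraries and 25 at most 1/3 of it. Divided by the library's median over genes 16 were high, and with genes of at least 5000 bp 3 were high and 13 low. The highest ran from GPR89B to FCGR1A (chromosome 1, 147928420 to 149812370) at 5.03, 5.34 and 4.37, and from SLC2A12 to MAP7 (chromosome 6, 133987581 to 136550422) at 3.97, 4.06 and 3.46. Windows on chromosome 18 from MBD1 to DCC (50266885 to 53535899) and from MTCL1 to APCDD1 (8705556 to 10489949) were also among the 8, and chromosome 18 as a whole stood at 2.14, 2.17 and 2.05. Spearman's rho between libraries across windows was 0.946, 0.885 and 0.881, and genes are not independent replicates.

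**Figure D5:**
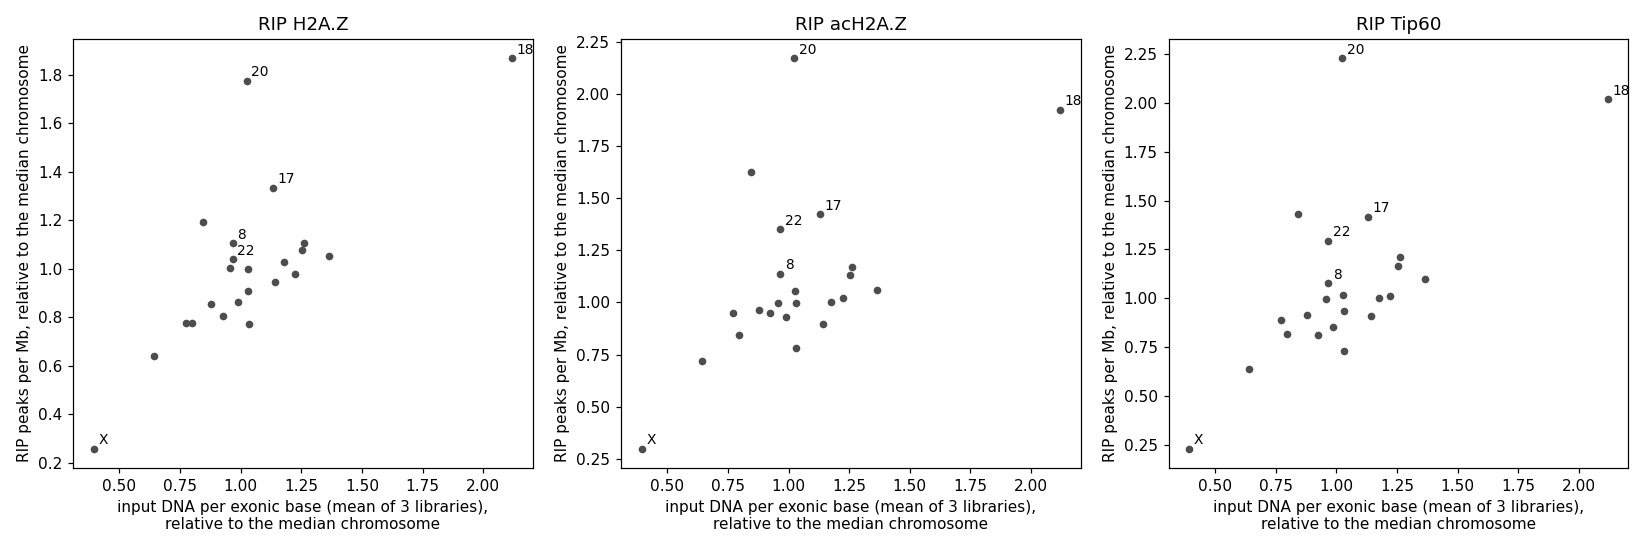
RIP peaks per Mb of each chromosome against input DNA per exonic base, both relative to the median chromosome, for H2A.Z, acH2A.Z and Tip60, with 6 chromosomes named. Chromosome 18 lies high on both axes, with peak densities of 1.87, 1.93 and 2.02, and chromosome 20, with 1.78, 2.17 and 2.23, has input near the median.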

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

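Of the tests in this part, the one on exchanged labels was chosen after the result was seen, and the one on the yield of the immunoprecipitation before.

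The marks moved in opposite directions in the library labelled siMyc. Genes with an H2A.Z end peak were 1.63 times as many as in siNTC and genes with an acH2A.Z end peak 0.541 times as many, and this difference between the marks was not tested, with 1 library each. Peaks also lay outside the chromosomes compared, in lists whose peaks the authors had called over a control. The H2A.Z ChIP list in DRB held 2 peaks on the mitochondrial genome and the H2A.Z RIP list 5. On unplaced and alternate contigs the RIP lists held 166 peaks for H2A.Z, 987 for acH2A.Z and 808 for Tip60.

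The acH2A.Z siMyc library held only 3.55% of its tags in peaks, over 12.6 Mb with a mean of 24.5 tags per peak, against 39.9% over 24.2 Mb and a mean of 230 in siNTC, if tags are per 10000000. An exchange of the H2A.Z and acH2A.Z labels within siMyc would put many tags into peaks of the library labelled H2A.Z, but that library held 2.69%, which argues against it. A lower yield of the immunoprecipitation that scaled all peaks alike was to give a narrow spread of ratios, and the interquartile range of the log2 ratio at 8391 shared peaks was 3.85. The sums are over regions called separately, with median widths of 933 bp in siMyc and 1577 bp in siNTC. Per base, which the prediction did not cover, the range was 2.71, still above the bound set beforehand for a wide spread. Over all acH2A.Z siMyc peaks, however, the median was 15.4 tags and the lowest count 6.83, against a median of 101 in siNTC. Counts held up near this floor could widen the spread even if the yield fell alike at all peaks. The regions also differ between the lists, and each group has 1 library, so this test cannot decide the question. A lower yield, even or uneven, and the different scaling of the control in these lists remain open. A biological loss of acetylation in the cells labelled siMyc also remains open and was not tested.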

How the results depend on the processing

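Alternatives using the common lowest tag count, and those setting RIP shares within deciles of gene length or against all genes with no RNA counts, were chosen after the data were seen, and the others before. No paired analysis was possible because each group holds 1 library. For 46 results that answer a comparison, 164 alternatives were run, of which 87 stayed within the limits set, 64 moved and 13 changed direction. For list medians these were 210, 71 and 1 of 282, and for named genes 1110, 368 and 0 of 1478. Direction was counted as changed only for medians and genes at least 2-fold in size. By sign alone, 25 list medians and 25 named genes turned under at least 1 alternative, 22 and 25 of them after centring and 14 and 12 after rescaling. The ratios of genes with end peaks in siMyc to siNTC, 1.63 and 0.541, kept their direction under every alternative run. The cause was not tested for any of the changes below, except where a shorter list or fewer genes lowers a count by construction or tied genes are named.

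With a mean of at least 5 CPM, fewer genes were tested. Then 499 genes were higher and 4376 lower in DRB, 3724 lower in ActD, 2111 lower in ActD than in DRB, and 465 higher and 1159 lower in nascent than in total RNA. The correlation of the inhibitors was 0.190, with 2223 genes lower in both, and rho with length was 0.198 in DRB and -0.228 in ActD. A pseudocount of 0.1 gave rho of 0.184 and -0.134. After centring, 3013 genes were higher and 3204 lower in DRB, 3652 and 3827 in ActD, 1434 were lower in nascent than in total RNA, and the median of nuclear long non-coding RNAs in DRB turned to 0.11. After rescaling, 2147 genes were higher in DRB and 2897 in nascent than in total RNA.

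With the higher-scoring part of each list, shared peaks of DMSO and DRB were 39.3% for H2A.Z and 53.8% for acH2A.Z, those of DMSO and ActD 55.2% for acH2A.Z, and those of siNTC and siMyc 29.3% for H2A.Z and 35.8% for acH2A.Z. H2A.Z peaks overlapped acH2A.Z peaks in DMSO at 43.7%, and RIP peaks overlapped at 7.14%, 14.3% and 20.9%. The highest decile then had acH2A.Z end peaks at 47.1%. The ratio of genes with acH2A.Z in ActD to DMSO turned to 1.22, and the median of genes that lost acH2A.Z minus that of genes that kept it turned to 0.017 in DRB and -0.17 in ActD.

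With lists limited to the shortest, ratios of genes to DMSO turned to 0.650 for H2A.Z in DRB, 0.273 for H2A.Z in ActD and 0.732 for acH2A.Z in DRB, and the ratio of acH2A.Z to H2A.Z turned to 0.750 in DMSO and moved to 3.42 in siNTC. Shared peaks were 27.3% and 9.35% for H2A.Z in DRB and ActD, 58.6% and 59.2% for acH2A.Z, 18.7% and 51.0% for siNTC H2A.Z and acH2A.Z, 7.92% and 15.1% between the marks in DMSO and siNTC, and 4.29%, 9.51% and 18.9% for RIP. With the common lowest tag count, the ratio of H2A.Z genes to DMSO was 1.12 in DRB and turned to 0.0750 in ActD, shared peaks were 41.0% and 3.88%, those of acH2A.Z 94.1% and 76.5%, and those of acH2A.Z in siNTC and siMyc 49.9%.

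With reciprocal overlap of 50%, shared peaks were 32.4% and 9.83% for H2A.Z in DRB and ActD, 72.6% and 63.3% for acH2A.Z, 17.9% and 23.2% for siNTC, and 0.951% and 6.99% between the marks in DMSO and siNTC. With ends of 500 bp the ratio of H2A.Z genes in ActD to DMSO turned to 0.812, from 1.00. With ends of 2500 bp the highest decile had acH2A.Z at 95.2%. Counted at gene ends, RIP genes numbered 3126, 8782 and 7862. Ranked by total RNA, the share of genes with a RIP peak in the highest decile as a ratio to the lowest moved to 1.57 for H2A.Z and turned to 0.927 for acH2A.Z. The first 4 deciles of total RNA had a median of 0 CPM, so their order is arbitrary, and against all 6758 genes with no total RNA counts the ratios were 1.87 and 1.05, so the turn rests on that order. With shares averaged over deciles of gene length, the ratio by nascent RNA moved to 1.60 for H2A.Z and turned to 0.891 for acH2A.Z. Within deciles of gene length in place of expression, the difference in acH2A.Z ends between genes with and without a RIP peak turned to 19.1 points for H2A.Z and 16.2 for Tip60 and stayed at -3.14 for acH2A.Z. In the input, dividing by the median gave 16 high windows, and genes of at least 5000 bp gave 3 high and 13 low. Shallow input and 1 library per group limit all of these.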

Other observations

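Of the tests in this part, those on RIP peaks and input DNA were chosen after the result was seen, and those on the nascent ratios before.

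Markers of other lineages were low in RNA. In total RNA the median of the neutrophil and monocyte list was 0.0789 CPM, with CYBA highest at 32.8 CPM, and the medians of the erythroid, lymphoid and epithelial lists were 0 CPM. EPOR reached 3.39 CPM, CD4 59.9 CPM and MUC1 0.946 CPM. In nascent RNA under DMSO, MKI67 led the G2/M list at 5454 CPM, MYB the myeloid factors at 594.7 CPM and NCL the MYC targets at 3744 CPM, and MALAT1 stood at 6519 CPM.

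Nascent RNA ratios were large in both directions under both inhibitors. If few distinct molecules lay behind the treated libraries, the variance beyond read counting should be larger in low than in high genes. In the fourth and the highest decile that variance was 2.53 and 1.07 for DRB and 3.99 and 1.73 for ActD, and the smaller of the ratios, 2.30, lay above the bound of 2 set beforehand, so low complexity may account for part of the spread, although lowly expressed genes may also differ more in their response. A changed mitochondrial share of the total is not the whole cause, since 76.6% of the genes lower in DRB stayed lower after rescaling. A response to the inhibitors themselves stays open, because each was sequenced once.

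RIP peaks were dense over regions that are gained in the input DNA, with 62.6, 150 and 155 peaks per Mb for H2A.Z, acH2A.Z and Tip60 in 57 windows at 2 times the median or more, against 39.2, 105 and 101 in the other 1836. If DNA fragments in the RIP libraries were the source, peaks in genes with no RNA counts should follow the input, but Spearman's rho across windows was 0.0895, 0.110 and 0.191. The first lay below the lower bound and the others between the bounds, and each outcome had been set for all 3 antibodies, so neither was met. If higher RNA levels from these regions were the source, silent genes should hold few peaks. Over 2103 such genes the density was 0.398 times that of the highest decile of expression for H2A.Z but 1.22 and 0.634 times for acH2A.Z and Tip60. The first lay between the bounds and the others above the upper bound, so neither outcome was met for all 3. The 2 explanations cannot be told apart here, because no outcome held for every antibody.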
